A study of Mus musculus with 6 samples.

How the data were processed

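Haematopoietic stem cells (HSC) sorted from bone marrow as CD150+ CD48- KSL cells of Lig4mut mice and of wild-type (WT) littermates, 6 to 8 weeks of age, were profiled on 1-colour whole-genome mouse expression arrays of Affymetrix, with 3 biological replicates per genotype and 6 arrays in all. Per the labels, RNA was extracted with Trizol, and the series design text names the Ovation Pico WTA System V2 amplification kit, while the labelling protocol in the labels names the standard Affymetrix cRNA method. Whether a replicate is 1 mouse or a pool of mice is not given in the sources used here.

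The deposited values are log2 expression values per probe set, made by the authors with RMA per the submitters' processing notes, which give no version. The lowest value is exactly 3 on every array, so a floor was set before deposit, and its origin is not given in the sources used here. A value at the floor is a bound and has no order among others at the floor. An array has no sequencing depth, and the number of arrays limits the precision.

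The table holds 45101 probe sets, of which 64 are controls. Probe sets were named through GEO's platform annotation, in which 34958 probe sets name 1 gene, 932 name several and 9160 have no entry. Symbols of 34754 probe sets were updated through the gene identifier to NCBI's mouse gene table for GRCm38.p6, which was used for names and gene order, and 204 kept the annotation's symbol. Control probe sets and those with several genes or none were left out, and each of 18193 genes was represented by the probe set with the highest mean over the 6 arrays. For 9182 genes there was 1 probe set.

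The deposited array distributions differed between the arrays, so the log2 values were quantile normalized across the 6 arrays before any test, as had been laid down for that case. Differences are Lig4mut minus WT on the log2 scale, with a standard error (SE) from limma. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated statistics, two-sided, no filter on dim genes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The exact permutation test of a single gene with 3 arrays against 3 cannot give a p below 0.1, so no such test was run.

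The 36 gene lists, with 876 entries, come from textbook knowledge of HSC, DNA repair, the cell cycle, stress responses, metabolism and the other cell types a sort could hold. Measured members came to 779, and 34 lists were tested. The list of sex-linked genes served to check the animals, and the list of replication-dependent histones had 2 of 17 members measured, under the minimum of 5. Lists were compared with all other genes by limma's camera with its preset inter-gene correlation of 0.01, two-sided, adjusted over the 34 lists, and again with a correlation estimated per list. The rotation test fry asks whether a list's genes move on balance in 1 direction, without comparing them with other genes. Members were also adjusted over the list alone, with no further adjustment over the 34 lists. In these data 19.7% of all genes lay at an unadjusted p under 0.05 by limma. Lists taken at random can therefore also hold members past the threshold adjusted over the list alone. Each list's median was set beside those of 10000 random lists matched on mean level.

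The genes named in the text were chosen by a rule. It takes Lig4 first, then up to 12 genes higher and 12 lower past the adjusted threshold whose Lig4mut arrays all lie on 1 side of the WT arrays, by fold. Each direction is filled to 12 with the smallest unadjusted p among genes with an absolute log2 difference of at least 1 and the same separation, and such genes are given as values. Predicted genes and clones were passed over, and of each list described up to 4 members with the smallest p are named. Other genes are named after their values were seen, and the text says so.

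The test was tried on data simulated with the spread of these arrays and 18193 genes, 200 of them changed. Over 20 simulations it called 2.6% of the genes with a log2 change of 1, 19.6% of those with a change of 2, 40.7% with a change of 3 and 54.6% with a change of 4, none with the wrong sign. Calls on unchanged genes averaged 4.1 per simulation. A shift of the stem cell list by -0.5 was called in 20 of 20 simulations. Genes were drawn independently, with a spread pooled over both genotypes. The simulations therefore do not cover list members that vary together or a spread that differs between genotypes.

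The test, the gene lists, the naming rule and most alternatives were fixed before the data were examined. These alternatives were the replicate number as a block, leaving out each array, centring each array on its median with no quantile step, leaving out genes under the 40th percentile of mean level, averaging a gene's probe sets, a variance trend with robust moderation, array weights, testing every probe set, other thresholds, an estimated inter-gene correlation and fry. Chosen after the data were seen were the deposited values with no further step, also for fry, cyclic loess, and the pattern of sex-linked genes as a covariate.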

Results

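Gene expression was measured in HSC, the cells that sustain blood formation, from Lig4mut mice and WT littermates. Lig4 encodes DNA ligase IV, which seals DNA double-strand breaks in non-homologous end joining, and the series asks what the enzyme means for the upkeep of HSC. There were 3 arrays per genotype. Deposited array medians lay between 6.29 and 6.34 in WT and between 5.97 and 6.05 in Lig4mut (log2), and the share of probe sets at the floor between 5.59% and 5.67% in WT and between 6.45% and 6.54% in Lig4mut. Arrays correlated at r = 0.940 to 0.950 within WT, 0.849 to 0.864 within Lig4mut and 0.866 to 0.900 between genotypes, across probe sets, which are not independent replicates. The median SD of a gene was 0.283 between WT arrays and 0.452 between Lig4mut arrays.

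The targeted gene was low in every Lig4mut array. Lig4 had log2 levels of 7.53, 6.66 and 7.63 in WT and of 4.97, 3.16 and 3.10 in Lig4mut, the last 2 close to the floor of 3. The difference was -3.53 ± 0.61 (SE, n = 3 per genotype), 11.5-fold, with the Lig4mut arrays all below the WT arrays. It did not pass the threshold over all genes (limma, adjusted p = 0.13) and passed it adjusted over the list alone among the 15 measured genes of non-homologous end joining (adjusted p = 0.0281). Lig4 has 1 probe set on this array, and the labels do not say what the mutation is, so whether the probes lie in an altered part of the gene is not known here.

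Klhl4 and Trim6 fell in Lig4mut HSC and were the 2 genes of 18193 past the threshold. Klhl4, a gene of the Kelch-like family, went from 7.55 ± 0.29 (SD, n = 3) in WT to the floor in all 3 Lig4mut arrays, at least 23.5-fold lower (log2 -4.55, a lower bound in size; limma, adjusted p = 0.0213). The floor sets the spread between its Lig4mut arrays to 0, so this p rests on the WT arrays and on the moderation across genes. Trim6, which encodes a tripartite-motif ubiquitin ligase, went from 6.61 ± 0.09 to 3.84 ± 0.13, 6.83-fold lower (log2 -2.77 ± 0.14 SE; limma, adjusted p = 0.031). Both have 2 probe sets, and both probe sets of each were lower in Lig4mut. The means over them were -2.53 for Klhl4 and -1.45 for Trim6 (limma, adjusted p = 0.11 for both). The fall was thus much smaller in the other probe set of each gene. Without any 1 of the 6 arrays, with the mean of a gene's probe sets or with the pattern of sex-linked genes in the model, 0 genes passed by limma, with 2301 to 4096 genes at an unadjusted p under 0.05.

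The other genes named by the rule are given as values, since none passed the threshold (limma, adjusted p = 0.125 for each). Among the lower ones were Arhgap33 (log2 -3.42 ± 0.24 SE, 10.7-fold), and Ly96, the partner of the endotoxin receptor (at least 19.2-fold lower, with a log2 difference of -4.26 that is a lower bound in size, since 2 of 3 Lig4mut arrays were at the floor). Rnd2 differed by -2.86 ± 0.27, the kinase gene Stk17b by -2.20 ± 0.25 and the homeobox gene Hoxa10 by -1.94 ± 0.17, the last with 1 of its 2 probe sets in the other direction and a mean over both of -0.858. Suox, Slc12a5, Isca2, Fnbp1l and Pcdhb3 had values between -2.04 and -1.30. Suox was at the floor in 2 of 3 Lig4mut arrays, so its value is a lower bound in size, and Slc12a5 had 1 of its 2 probe sets in the other direction and a mean over both of -0.869.

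The 12 genes on the higher side differed by 1.02 to 2.10, or 2.03-fold to 4.29-fold. Pop7, a subunit of ribonuclease P, had the largest difference (2.10 ± 0.22 SE, 4.29-fold), followed by Dtx4, a Deltex ubiquitin ligase of Notch signalling (1.96 ± 0.17, 3.89-fold). Dtx4 passed adjusted over the list alone among 26 measured genes of TGF-beta, Notch and Wnt signalling (adjusted p = 0.0017), a list that camera did not call (adjusted p = 0.902). Cyp24a1, the vitamin D hydroxylase, differed by 1.61 ± 0.16, and Irf7, a transcription factor of the interferon response, by 1.05 ± 0.12. The others were Pde1a, Apba1, Cryba2, Grrp1, Kcnc1, Dact2, Ssbp4 and Krt33a. Of these, the crystallin gene Cryba2 and the keratin gene Krt33a belong to families taken as silent in blood cells. For 9 of the 12 the WT mean lay under the median WT level of all genes, 6.86. With the mean of a gene's probe sets Dtx4 was at 1.17, Cyp24a1 at 1.05, Kcnc1 at 0.412, Pde1a at 0.529 and Apba1 at 0.48, the last 2 with a probe set in the other direction. The median difference of all genes was 0.177 in this normalization, and relative to it the 12 differed by 0.845 to 1.92.

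**Figure D1:**
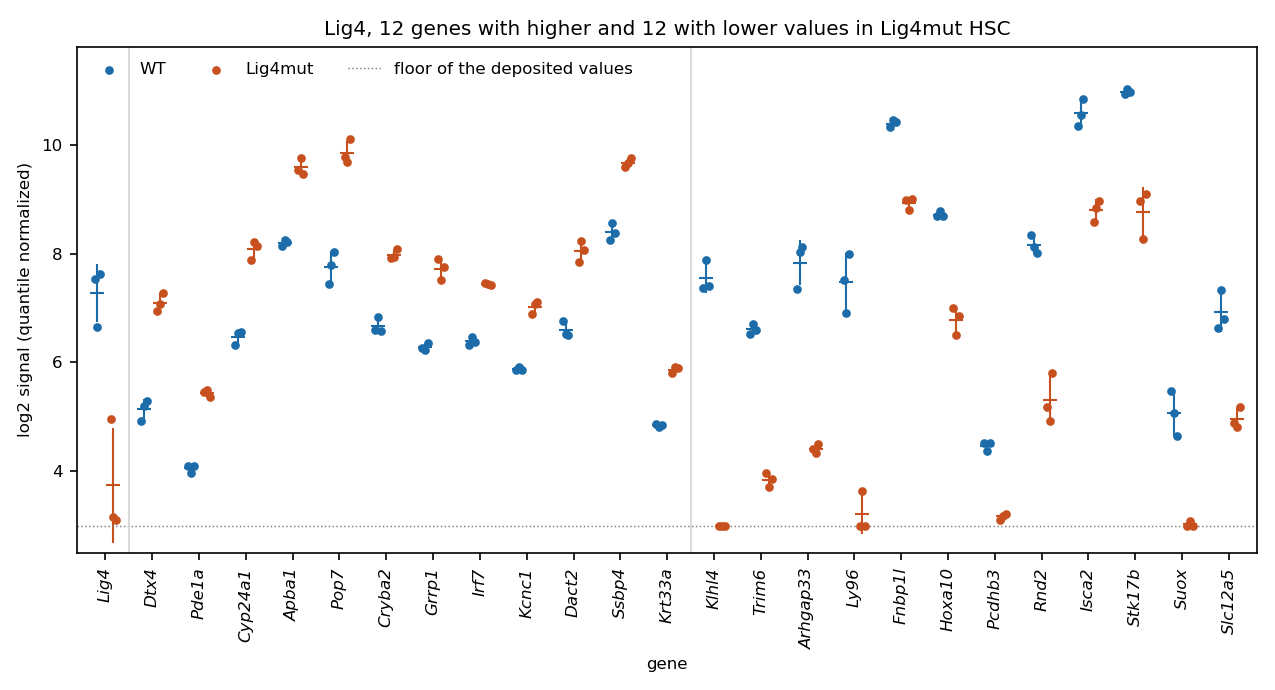
Log2 signal (vertical axis, quantile normalized) of Lig4, the 12 named genes with higher and the 12 with lower values in Lig4mut (horizontal axis). Points are single arrays, blue for WT and orange for Lig4mut, the horizontal dash is the mean of 3 arrays and the vertical line 1 SD; in every gene shown the 3 Lig4mut arrays lie on 1 side of the 3 WT arrays, and Klhl4 lies at the floor of 3 in all Lig4mut arrays.

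Many more genes differed at the unadjusted level. At an unadjusted p under 0.05 there were 3586 genes, 2826 higher and 760 lower in Lig4mut, where chance alone gives about 910. The values as deposited, with no further quantile step, gave 2211 genes, 1225 higher and 986 lower, so the share of higher genes was 78.8% with the step and 55.4% without it, and it was 87.7% after centring on array medians and 66.6% with cyclic loess. Without WT replicate 2 the count was 2301, 1759 of them higher. The 3 arrays of each genotype did not overlap for 4854 genes, 26.7% against the 10% that chance gives. The higher genes at this level were dim, with a median level of 6.05, and the lower ones bright, with a median level of 8.32.

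In this normalization genes of HSC identity lay lower in Lig4mut relative to the other genes. Camera did not call the list in the values as deposited (adjusted p = 0.0785), with median centring (0.0649) or with cyclic loess (0.0875). Nor did it with dim genes left out (0.061). Of 33 measured members of the haematopoietic stem cell list, 22 had lower and 11 higher values, with a median of -0.53 relative to all genes (limma's camera, adjusted p = 0.00172; adjusted p = 0.302 with an estimated correlation). The mean level of the list was 10.06 to 10.18 in the WT arrays and 10.05, 9.52 and 9.74 in Lig4mut replicates 1, 2 and 3, so replicate 1 was close to WT. None passed the threshold over all genes or adjusted over the list alone. Meis1, a homeobox transcription factor of HSC, was at 10.86 ± 0.28 (SD, n = 3) in WT and 9.22 ± 0.75 in Lig4mut (log2 -1.65 ± 0.42 SE, and -1.07 as the mean of its probe sets). Kit, the stem cell factor receptor, differed by -0.95 ± 0.26 (-0.613 with arrays centred on their medians) and Gprasp2 by -1.68 ± 0.56. Nupr1, a stress-response gene on the list, had higher values instead, with 10.84 ± 0.55 against 8.54 ± 1.13 (2.31 ± 0.65 SE). Without Lig4mut replicate 2, the array with high granulocyte transcripts described further on, the list's median was -0.224 relative to all genes (camera, adjusted p = 0.0061, within a range of 9.18e-05 to 0.0875 over the 15 alternatives that keep the preset correlation).

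The quiescence regulators lay lower in the same way, and camera likewise did not call them under the other scalings. Of 19 members, 15 had lower values, with a median of -0.66 relative to all genes (camera, adjusted p = 0.00596; adjusted p = 0.302 with an estimated correlation). Rbl2, a retinoblastoma-family pocket protein that restrains the cell cycle, differed by -1.70 ± 0.33 SE, and Cdkn1c, the cyclin-dependent kinase inhibitor p57, by -0.78 ± 0.34. The median was -0.384 without Lig4mut replicate 3 (adjusted p = 0.0107) and -0.311 with the mean of probe sets (0.0134), in a range of 0.00116 to 0.0875 over the alternatives that keep the preset correlation. The list's mean level in WT replicate 1, 9.42, lay below that of Lig4mut replicates 2 and 3, 9.60 and 9.50. This list shares 4 genes with the stem cell list and 3 with the list of immediate early genes. By fry the quiescence genes moved down on balance (adjusted p = 0.0261, and 0.0733 in the values as deposited), and the stem cell list did not pass (adjusted p = 0.235).

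Immediate early genes, which respond to handling of cells, had 23 of 29 members lower, with a median of -0.49 relative to all genes (camera, adjusted p = 0.00861; adjusted p = 0.731 with an estimated correlation). Of the members, 2 passed the threshold adjusted over the list alone. Egr2 was 8.24-fold lower (log2 -3.04 ± 0.51 SE, adjusted p = 0.0225) and Fosl1, a subunit of the transcription factor AP-1, 1.94-fold higher (0.96 ± 0.13, adjusted p = 0.0165). Fosl1 has 1 of its 2 probe sets in the other direction and was at 0.292 as the mean of both, and at 0.654 in the values as deposited. Egr3 and Nr4a3 had values of 1.13 ± 0.33 and 0.98 ± 0.28, and of 0.0655 and 0.468 as the mean of probe sets, of which 1 each went the other way. The list's mean level was 9.66, 10.74 and 10.70 in WT replicates 1, 2 and 3 and 9.51, 10.35 and 10.48 in those of Lig4mut, so the genotypes overlapped. Without Lig4mut replicate 1, in which 17 of the 29 genes were lowest, this list did not pass (median -0.296, adjusted p = 0.269, in a range from 1.34e-05 over the alternatives that keep the preset correlation), nor without WT replicate 2 (adjusted p = 0.104) or WT replicate 3 (adjusted p = 0.0744).

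Chromatin regulators of stem cells were lower for 17 of 24 members, with a median of -0.40 relative to all genes (camera, adjusted p = 0.0423; adjusted p = 0.405 with an estimated correlation). The DNA methyltransferase genes Dnmt3b and Dnmt3a differed by -0.97 ± 0.24 SE and -0.81 ± 0.22, and Tet2, which encodes a methylcytosine dioxygenase, by -1.82 ± 0.48. Ezh2, the histone methyltransferase of Polycomb complex PRC2, had higher values, by 0.91 ± 0.24. With the mean of probe sets Dnmt3b was at -0.548, and with arrays centred on their medians Dnmt3a was at -0.476. None passed adjusted over the list alone. The list did not pass without WT replicate 1 (adjusted p = 0.0606), WT replicate 3 (0.0527), Lig4mut replicate 1 (0.149) or Lig4mut replicate 2 (0.115), in a range of 0.0134 to 0.226 over the alternatives that keep the preset correlation, and its median was -0.253 with dim genes left out.

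These 4 were the lists past the camera threshold of 34 tested, and no member of any list passed the threshold over all genes. Adjustment over a list alone takes no account of the number of lists. None of the 4 calls held with an estimated correlation, and fry called 5 lists, the quiescence regulators down and 4 lists up. Fry tests against 0 and not against the median of all genes, and in the values as deposited it called 0 lists, with 2211 genes at an unadjusted p under 0.05 by limma. With the values as deposited, centred on array medians or normalized by cyclic loess, 0 lists passed, although the medians of the 4 stayed below that of all genes. The stem cell list lay at percentile 1.3 of random lists of the same mean level, the quiescence list at 0.27, the immediate early list at 0.2 and the chromatin list at 18.5.

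**Figure D2:**
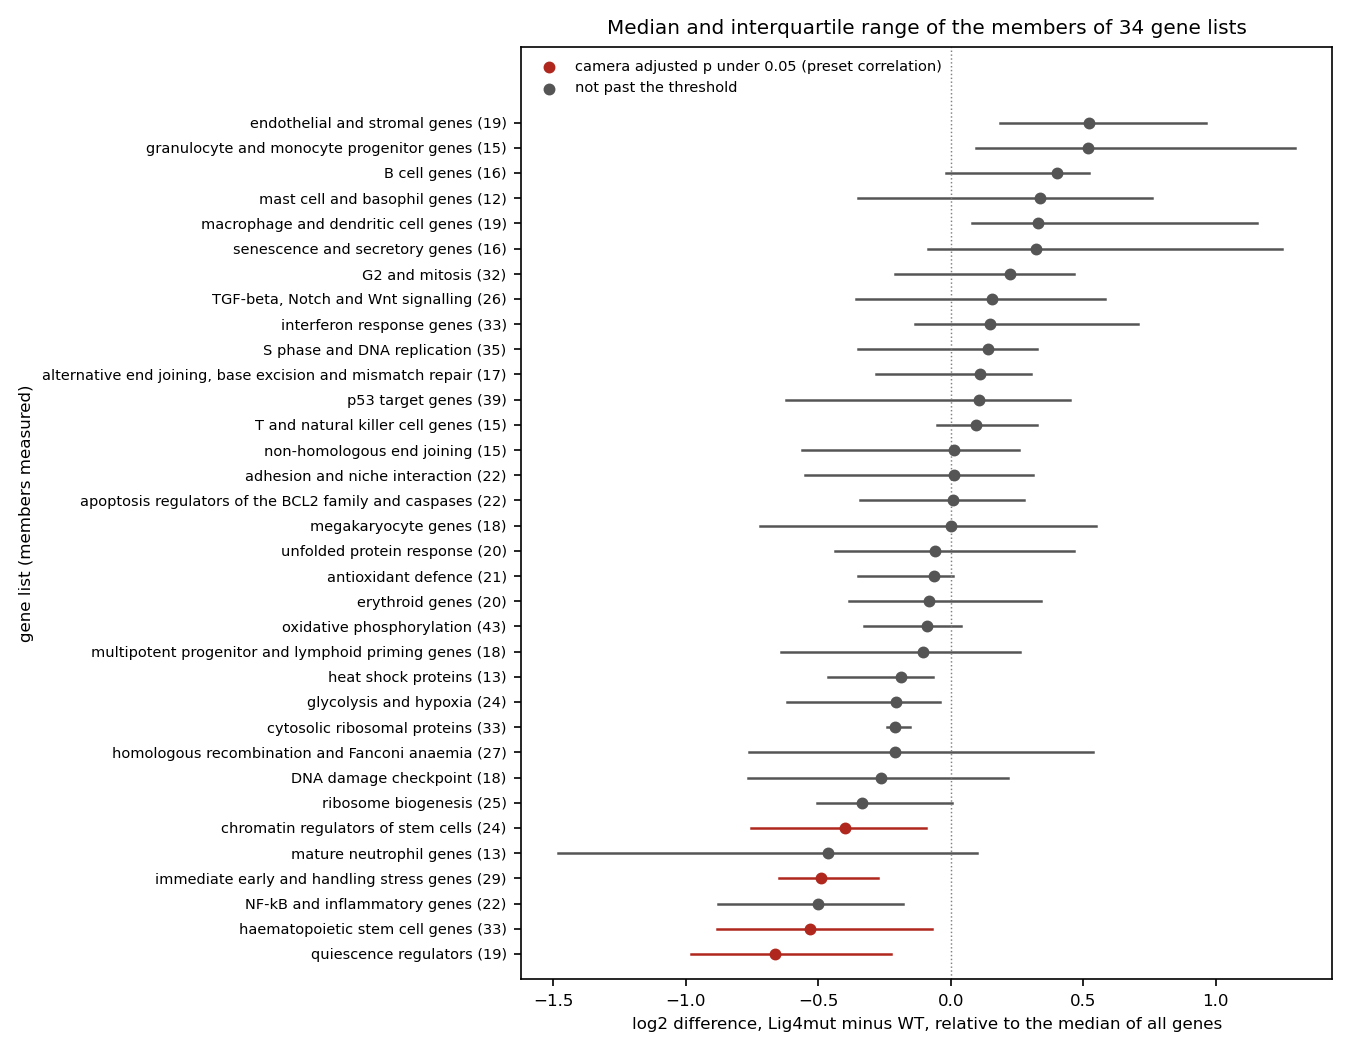
Log2 difference, Lig4mut minus WT, relative to the median of all genes (horizontal axis) for the 34 tested gene lists (vertical axis, number of measured members in brackets). Dots are medians of the members and lines their interquartile range, red for the 4 lists past the camera threshold with the preset correlation, whose medians lie between -0.66 and -0.40; none of them passed with an estimated correlation.

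Genes of the p53 response, which DNA breaks activate, were not called relative to other genes (camera, adjusted p = 0.936). They moved up on balance by fry (adjusted p = 0.0127), which was lost in the values as deposited (adjusted p = 0.157). Of 39 members, 25 had higher values, 6 of them at an unadjusted p under 0.05, a share of 15.4% against 15.5% of all genes, and none passed adjusted over the list alone. Gadd45a, a growth arrest gene, was at 6.39 ± 0.56 (SD, n = 3) in WT and 8.99 ± 1.17 in Lig4mut (log2 2.60 ± 0.67 SE), and Apaf1, the apoptosome scaffold, differed by 2.01 ± 0.55. The exonuclease gene Aen differed by 1.67 ± 0.52 and Phlda3 by 1.16 ± 0.40. Of the probe sets of Apaf1 1 of 2 went down and of those of Aen 2 of 4, and the means over them were 0.379 and 0.742. Cdkn1a and Mdm2, the best-known targets of p53 and picked after their values were seen, had differences of 1.03 ± 0.66 and -1.85 ± 0.87. Cdkn1a was at 0.348 without WT replicate 1 and 1.57 without WT replicate 2, and Mdm2 at -1.02 without Lig4mut replicate 3 and -1.09 as the mean of probe sets, in a range from -2.72. In the repair lists Lig4 stood alone as a member past the threshold adjusted over the list alone. Xrcc6, the Ku70 subunit, differed by -1.09 ± 0.61 (-0.466 as the mean of its 2 probe sets, of which 1 went up), Trp53bp1 by -0.53 ± 0.31 (-0.214 without Lig4mut replicate 1 and -0.984 as the mean of probe sets) and the end-processing gene Aptx by 0.83 ± 0.51 (0.49 without Lig4mut replicate 1 and 1.39 without Lig4mut replicate 3). Camera gave adjusted p = 0.423 for non-homologous end joining, 0.283 for homologous recombination and Fanconi anaemia, 0.705 for the other repair pathways and 0.178 for the damage checkpoint.

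Of the cell division genes, Bub1b and Hmmr were higher in Lig4mut past the threshold adjusted over the list alone among 32 genes of G2 and mitosis (adjusted p = 0.0275 for both). Over all genes neither passed (limma, adjusted p = 0.125 for Bub1b and 0.13 for Hmmr). Bub1b, a spindle checkpoint kinase, was 3.23-fold higher (log2 1.69 ± 0.26 SE) and Hmmr, a spindle protein, 2.87-fold higher (1.52 ± 0.26). Cdca8 and Aspm had differences of 0.69 ± 0.29 and 1.76 ± 0.77. These values depend on the probe set chosen, since as the mean of probe sets Bub1b was at 1.11, Hmmr at 0.326 with 1 of 5 lower, and Aspm at 0.0084 with 2 of 5 lower. In all, 24 of the 32 had higher values, with a median of 0.22 relative to all genes (camera, adjusted p = 0.586), which ranged from 0.0814 to 0.428 over the alternatives. Among 35 genes of S phase, 24 had higher values and none passed adjusted over the list alone (camera, adjusted p = 0.948). Cdc45 was at 1.03 ± 0.21, Rfc4 at 0.66 ± 0.19 and E2f1 at 1.01 ± 0.42, while Pole went the other way, at -1.87 ± 0.67.

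Several genes of antigen presentation and of B cells had higher values in Lig4mut. Of 19 macrophage and dendritic cell genes, 17 were higher and 4 passed adjusted over the list alone, namely the class II genes H2-Ab1 (4.85-fold, log2 2.28 ± 0.54 SE) and H2-Aa (3.48-fold, 1.80 ± 0.45), the scavenger receptor Marco (1.72-fold) and the plasmacytoid dendritic cell gene Siglech (1.73-fold). The list moved up by fry (adjusted p = 0.0127, and 0.0733 in the values as deposited) and missed the threshold by camera (adjusted p = 0.0712), which it passed with the mean of probe sets (0.0256) and with dim genes left out (0.039, with a median relative to all genes of 1.02 over 10 members in place of 0.328), in a range up to 0.181. Its mean level was 6.24 to 6.65 in the WT arrays and 7.07 to 7.26 in the Lig4mut arrays. Of 16 B cell genes, 14 were higher, and Ighm, the immunoglobulin heavy chain of IgM (1.79-fold), and the transcription factors Ebf1 (1.67-fold) and Pax5 (1.60-fold) passed adjusted over the list alone, while Igll1 had a difference of 1.47 ± 0.40. The B cell list passed neither camera (adjusted p = 0.096) nor fry (adjusted p = 0.16), although it passed camera without Lig4mut replicate 1 (adjusted p = 0.0191, in a range up to 0.447), and its median of 0.401 relative to all genes was 0.196 without Lig4mut replicate 2, 0.247 without Lig4mut replicate 3 and 0.115 with the mean of probe sets. Both lists are dim, with mean levels of 6.79 and 5.98, and gene families taken as silent in blood cells had a median difference of 0.332 in the same normalization. In the values as deposited Ebf1 was at 0.418, Pax5 at 0.359, Marco at 0.478 and Siglech at 0.495 in place of 0.74, 0.68, 0.78 and 0.79. As the mean of probe sets Ebf1 was at 0.185, Ighm at 0.486 and Igll1 at 0.931.

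In the interferon response list 26 of 33 genes had higher values, and Irf7 passed adjusted over the list alone (adjusted p = 0.00706). In the values as deposited Irf7 was at 0.783 in place of 1.05. Ifit3 differed by 1.29 ± 0.28 SE, Oas2 by 1.46 ± 0.42 and Ly6e by 0.43 ± 0.15 (0.731 with arrays centred on their medians). The list moved up by fry (adjusted p = 0.0261, and 0.0733 in the values as deposited) and was not called relative to other genes (camera, adjusted p = 0.377). Among 22 NF-kB and inflammatory genes, 17 had lower values, and 3 passed adjusted over the list alone (adjusted p = 0.0294 for each). These were the chemokines Cxcl1 (3.46-fold lower) and Cxcl2 (2.64-fold lower) and the NF-kB subunit Nfkb2 (2.30-fold higher). Birc3 had a difference of -1.29 ± 0.45, and the list missed the threshold (camera, adjusted p = 0.096), which it passed without Lig4mut replicate 3 (adjusted p = 0.0345, in a range up to 0.738). As the mean of probe sets Cxcl1 was at -0.922, Nfkb2 at 0.757 and Birc3 at -0.797.

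Transcripts of other cell types varied between single arrays. The genes Prg2, Epx, S100a9, Sparc, Nid1, Xist and Eif2s3y were picked after their values were seen. The eosinophil granule genes Prg2 and Epx stood at 12.4 and 11.4 in Lig4mut replicate 2 and at 6.21 or lower in the other 5 arrays. S100a9, a neutrophil gene, was at 11.3 to 11.7 in the WT arrays and at 6.00, 13.1 and 6.49 in Lig4mut replicates 1, 2 and 3. Endothelial transcripts were low in WT replicate 1, with Cdh5 at 6.80 there against 10.1 to 11.6 elsewhere, Sparc at 8.70 against 11.9 to 12.4, and Nid1 at 3.97 against 8.12 to 10.6. The endothelial and stromal list had 18 of 19 genes higher in Lig4mut, with Pecam1 at 1.48 ± 0.41 SE, a median of 0.52 relative to all genes and no call by camera (adjusted p = 0.233). This median changed with single arrays, being 0.0235 without WT replicate 1 (adjusted p = 0.6, in a range of 0.0847 to 0.655), 0.216 without Lig4mut replicate 1 and 0.263 without Lig4mut replicate 2, and 0.93 without Lig4mut replicate 3 and 0.743 without WT replicate 3. Xist, the X-inactivation RNA, was at 12.5 in WT replicate 3 and 12.3 in Lig4mut replicate 2 and at 5.82 or lower in the other 4 arrays, and the Y-linked Eif2s3y ran opposite, so 1 array of each genotype had this pattern.

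**Figure D3:**
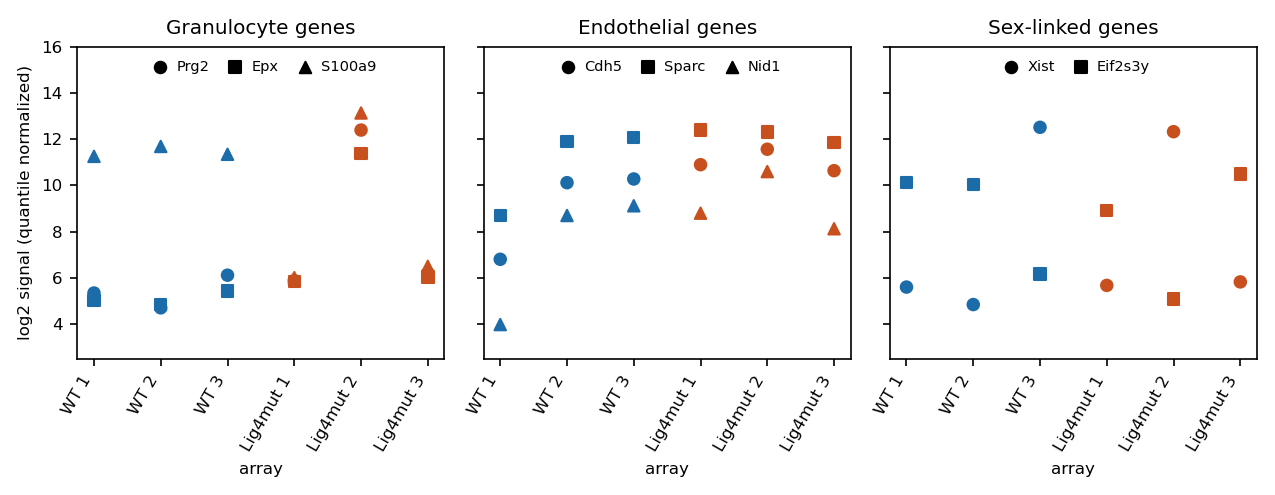
Log2 signal (vertical axis, quantile normalized) of granulocyte genes (left), endothelial genes (middle) and sex-linked genes (right) in each of the 6 arrays (horizontal axis), blue for WT and orange for Lig4mut, with a symbol per gene. Prg2 and Epx are high in Lig4mut replicate 2, Cdh5, Sparc and Nid1 are lowest in WT replicate 1, and Xist is high in WT replicate 3 and Lig4mut replicate 2.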

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

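Each test of an explanation in this part was chosen after the pattern it bears on had been seen and before the value it measures was computed, and the window of genes around Lig4 was reshaped because Lig4 lies near the end of its chromosome.

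Control probe sets, which no comparison above uses, were higher in all 3 Lig4mut arrays than in all 3 WT arrays. The bacterial transcripts that are added to every hybridization differed by 0.32 (bioB), 0.156 (bioC), 0.0928 (bioD) and 0.0377 (cre) on the log2 scale of the deposited values, and the probe set for the B1 repeat by 0.329. Probe sets for 18S ribosomal RNA and for the B2 repeat overlapped between the genotypes, with differences of -0.0204 and -0.0373. So did the 3' minus 5' values of Actb and Gapdh, a sign of RNA quality, which were -0.294 and 0.897 in WT and -0.0747 and 0.981 in Lig4mut, with differences of 0.219 and 0.084.

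The first pattern is the excess of higher genes at an unadjusted p under 0.05, 2826 against 760 lower. Families taken as silent in blood cells were receptors of smell, taste, pheromones and trace amines, keratins, crystallins and defensins. Their 204 genes, Cryba2 and Krt33a among them, were picked by symbol alone, and their silence in these cells was not checked. They were among the higher genes in 27.9% of cases, against 16.8% of other genes of the same mean level. The ratio was 1.66 (95% bootstrap interval 1.28 to 2.04), so signal that no expressed transcript accounts for may have risen in the Lig4mut arrays. The quantile step made here added to the difference of these families. Their median difference was 0.131 in the deposited values (interval 0.077 to 0.18) and 0.332 after the step. Neither bootstrap interval is taken as a measure of variation between arrays or mice. Without the step the excess shrank to 1225 against 986. What brought the rise that is left in the deposited values cannot be told from these values. A wider expression of normally silent genes in the mutant stays open and was not tested.

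The second pattern is the lower haematopoietic stem cell list. Its median lay at percentile 1.3 among 10000 random lists matched on mean level, lower than most such lists. This does not decide against a loss shared by all genes of that brightness, since the random lists carry no correlation between members. The NF-kB and mature neutrophil lists, which camera did not call, lay as low, at percentiles 0.19 and 1.05. RNA of granulocytes and eosinophils in Lig4mut replicate 2, where Prg2 reached 12.4 and Epx 11.4, may account for part of the size. Without that array the median was -0.224 in place of -0.531 relative to all genes. Its 95% bootstrap interval, -0.543 to -0.137, includes a shift of the original size. This interval is not taken as a measure of variation between arrays or mice, so whether the shift shrank is not settled by it. The CD48- KSL sort is meant to exclude granulocytes and eosinophils, but granule transcripts of such cells were high in Lig4mut replicate 2. The neutrophil gene S100a9 was also high in all WT arrays (11.3 to 11.7), against 6.00 and 6.49 in Lig4mut replicates 1 and 3. The list passed camera with the preset correlation without Lig4mut replicate 2 (adjusted p = 0.0061), but how much of the shift such RNA brings stays open. A change in HSC identity through the Lig4 genotype stays open as well and was not tested.

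The third pattern is the low Lig4 signal. A general loss of signals of that level is argued against by 1058 genes within 0.25 of the WT mean of Lig4, of which 1 (0.0945%) fell as far. A chromosome segment around Lig4 that differs between the mouse lines stays open. Its 100 nearest measured genes had a median absolute difference of 0.471, at percentile 73.6 of random windows (median 0.439), but such a median would hardly move if the segment altered Lig4 or a few neighbours alone. A lower Lig4 transcript level through the mutation and a sequence change under the probes stay open as well and were not tested.

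The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2 genes past the threshold and the highest other split 0, so 1 split gave as many. At an unadjusted p under 0.05 the real split gave 3586 genes and the highest other 933, and again 1 split gave as many. For lists by camera the real split gave 4 and the highest other 8, and 3 splits gave as many. The split with 8 lists sets WT replicate 1 and Lig4mut replicates 1 and 3 against the other arrays.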

How the results depend on the processing

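The deposited values (also for fry), cyclic loess and the sex-linked covariate were chosen after seeing the data. The plan's second quantile normalization is the setting used here and has no separate value. The number of genes past the threshold was 2, and it was 0 with the replicate block, with dim genes left out, with the mean of probe sets, with the sex-linked covariate, over every probe set (182 of 45037 at an adjusted p under 0.10, 88 higher and 94 lower) and without any 1 array (range 0 to 0), and 4 with a variance trend and robust moderation, which adds Arhgap33 and Ly96 (adjusted p = 0.0498 for both). Klhl4 and Trim6 kept their direction in every setting that tested them (both are among the dim genes), from -4.66 to -2.53 and from -3.02 to -1.45. The adjusted p of Klhl4 ranged from 0.00422 to 0.302 and that of Trim6 from 0.0144 to 0.362. Fewer arrays leave fewer residual degrees of freedom. With dim genes left out Klhl4 and Trim6 were not among the genes tested, so their calls could not recur. The mean of probe sets took in the other probe set of each gene, with its smaller fall. For the other settings the cause was not tested. The replicate numbers did not pair the samples (correlations of deviations 0.036, 0.01 and -0.032). Camera called 4 lists, 0 with the deposited values, with median centring, with cyclic loess or with an estimated correlation, 1 with dim genes left out (macrophage and dendritic cells), 5 with the mean of probe sets, 3 with the replicate block, which loses the chromatin list (adjusted p = 0.0664), and 2 to 6 without 1 array. Fry called 5, and 0 in the values as deposited, where the cause was not tested. The stem cell list kept a negative median relative to all genes, from -0.635 to -0.224, with adjusted p from 9.18e-05 to 0.0875 over the 15 settings with the preset correlation. The count at an unadjusted p under 0.05 was 2211 as deposited, 2378 with cyclic loess, 1449 with dim genes left out and 2301 to 4096 without 1 array. Over the scalings the median difference of all genes was 0.177 (quantile), 0.0201 (as deposited), 0.334 (median centring) and 0.0947 (cyclic loess). Median centring gave 3359 genes higher and 470 lower at that level, and cyclic loess 1584 and 794. The sign turned for Xist (0.288) without WT replicate 1 (-0.741), WT replicate 2 (-1.12) and Lig4mut replicate 2 (-1.91), in a range from -1.91 to 2.72, and with the mean of probe sets (-0.183), and for Eif2s3y (-0.609) without the same arrays (0.0701, 0.0225 and 0.933), in a range from -1.92 to 0.933. Signal near the floor limits what can be said of the size of a loss.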

Other observations

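Hypoxia and glycolysis genes went both ways in Lig4mut HSC. Bnip3, a mitophagy gene of the hypoxia response, had a difference of -2.40 ± 0.43 SE and Pdk1, the pyruvate dehydrogenase kinase, of -1.32 ± 0.41, while Ndrg1, also induced by hypoxia, had 2.23 ± 0.50 (1.42 as the mean of its probe sets). None of the 24 measured members passed adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.0929). Genes of the unfolded protein response were similarly mixed, with Manf at 0.87 ± 0.25, Sdf2l1 at 1.43 ± 0.47 and Creld2 at 1.11 ± 0.41, and Ddit3, which encodes the factor CHOP, at -0.89 ± 0.26 (camera, adjusted p = 0.695). Among adhesion and niche genes, Cxcr4, the chemokine receptor that holds HSC in the marrow, had -0.62 ± 0.15 (-0.284 with arrays centred on their medians) and the integrin gene Itga6 0.82 ± 0.26 (0.121 as the mean of its 2 probe sets, of which 1 went down; camera, adjusted p = 0.183).

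In the erythroid list Tal1, a transcription factor of HSC and red cell development, was 3.31-fold lower and the spectrin gene Sptb 1.67-fold higher, both past the threshold adjusted over the list alone (adjusted p = 0.0406), with camera at 0.653. In the values as deposited Sptb was at 0.426 in place of 0.74. The pro-apoptotic gene Hrk was 1.94-fold higher and passed adjusted over the list alone among 22 apoptosis regulators (adjusted p = 0.0106; camera, 0.961). Its difference was 0.643 in the values as deposited and 0.759 as the mean of probe sets, in place of 0.95. Selp, the platelet adhesion gene, had a difference of 2.75 ± 0.71 (1.58 as the mean of its probe sets) and did not pass in the megakaryocyte list (camera, adjusted p = 0.639). In the list of multipotent progenitor and lymphoid genes (camera, adjusted p = 0.695) Il12rb2 had 2.72 ± 0.67. Ighm passed adjusted over that list alone (limma, adjusted p = 0.0149). In the list of TGF-beta, Notch and Wnt signalling Dtx1, a second Deltex gene, had 0.73 ± 0.22 (0.295 as the mean of its 2 probe sets, of which 1 went down). Over the 30 lists that camera did not call, the adjusted p ranged from 0.0712 to 0.961 and the median relative to all genes from -0.502 to 0.522. In 6 lists, S phase among them, the median relative to all genes and the camera direction differed in sign, and in 5 the mean did.

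The genes of T and natural killer cells moved up on balance by fry (adjusted p = 0.0261, and 0.324 in the values as deposited), with a median of 0.095 relative to all genes (camera, adjusted p = 0.178). That relative median was 0.0123 without Lig4mut replicate 3 and 0.265 without WT replicate 3. The list is dim, with a mean level of 5.13. Its median difference of 0.272 was below the 0.332 of the gene families taken as silent in the same normalization. In the values as deposited it was 0.0642. Relative medians were 0.518 for granulocyte and monocyte progenitor genes (camera, adjusted p = 0.316), 11 of 15 of which were highest in Lig4mut replicate 2, 0.338 for mast cell and basophil genes (0.559), 0.321 for senescence genes (0.639, with Cxcl1 past the threshold adjusted over the list alone) and -0.464 for mature neutrophil genes (0.163). Without Lig4mut replicate 2 the median of the progenitor genes was 0.236 (adjusted p = 0.862, in a range from 0.0652), and the mature neutrophil genes were at -0.812 and passed camera (adjusted p = 0.00111, in a range up to 0.822), while without Lig4mut replicate 1 they were at -0.2. The senescence genes were at 0.113 without Lig4mut replicate 3 and 0.176 without Lig4mut replicate 1. Medians were -0.335 for ribosome biogenesis (0.0723, and 0.0244 without Lig4mut replicate 3, in a range up to 0.747), -0.209 for cytosolic ribosomal proteins (0.155) and -0.189 for heat shock proteins (0.198). In the values as deposited these medians were -0.163, -0.0518 and -0.0523. Those of oxidative phosphorylation (0.559) and antioxidant defence (0.423) were -0.0911 and -0.064 and had the other sign under at least 1 other scaling. The 2 measured histone genes were not tested.

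Larger sets of genes of the same cell types, picked after the fixed lists were seen, showed the same pattern of single arrays. They are not independent of the values above. Mpo, Elane, Ltf and Lcn2 were already members of fixed lists, and Nid1 was named above. Of 23 added endothelial genes 17 were lowest in WT replicate 1, with a mean level of 6.85 there and of 8.18 to 9.05 in the other 5 arrays. Of 16 added eosinophil and neutrophil genes 12 were highest in Lig4mut replicate 2, with a mean level of 7.91 there and of 5.49 to 6.17 in the others.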
